A study of Mus musculus with 30 samples.

How the data were processed

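Deposited were gene counts of total RNA from mouse bone marrow-derived macrophages, 30 libraries in 10 groups of 3 (wild-type and Rad21-/-, each unstimulated, LPS 2 h, LPS 8 h, and IFN-γ followed by LPS 2 h or 8 h). Per the labels, 200 nM 4-hydroxytamoxifen was given from 96 h for the ERt2-Cre, experiments were done on day 7, LPS and IFN-γ were used at 10 ng/ml, priming lasted 24 h, and stranded total RNA libraries were made from 750 ng of RNA per library. Per the submitters' processing notes reads were aligned with TopHat2 to mm9 and each deposited value is a raw count per gene; the counting tool, annotation and use of strand are not given. The count unit was checked on the files: every value is a whole number of 0 or more. The table holds 37620 gene IDs, of which 37205 were matched to a symbol and position in GENCODE vM1, and 415 were not. The labels mention ERCC spike-ins, but the table holds no spike-in rows. Intervals and floors given for counts cover counting error only.

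Groups came from the sample titles, and the tests, gene lists, naming rule and alternatives were set before the data were examined, except those stated to have been added afterwards. Genes were kept with edgeR's filterByExpr by group, leaving 14310. Counts were scaled by TMM and fitted by edgeR 4.0.16 (quasi-likelihood F test, 1 coefficient per group, all 30 libraries, common biological coefficient of variation 25.6%) under R 4.3.3, with Benjamini-Hochberg adjustment over all tested genes and a false discovery rate of 0.05. Contrasts were genotype at each stimulation and over the mean of the 5, LPS against unstimulated and primed against unprimed in each genotype, and the differences of these responses between genotypes, 18 in all. Fold changes are fitted log2 values with their standard error, and levels are CPM on TMM-scaled library sizes (library totals for sex-linked genes and AY036118), with the SD of 3 libraries. For a gene with 0 counts in a group the fold is a lower bound against 3 counts over the group. In 22 lists and comparisons a member had such a group, and with the bounds in place the median moved by more than 0.01 in 2, the late LPS response list before stimulation (-0.72 to -0.61) and at LPS 2 h in Rad21-/- (4.03 to 3.97).

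Gene lists (24, written from general knowledge) were tested by camera in limma 3.58.1 on voom values with a preset correlation of 0.01 between genes, adjusted over lists within a contrast, and again with the correlation estimated for each list; members called are also given with adjustment over the list alone. The lists cover cohesin, early and late LPS response, type I interferon response, interferon signalling, IFN-γ response, MHC class II, macrophage identity, alternative activation, proliferation, p53 targets, glycolysis and hypoxia, cholesterol synthesis, stress and unfolded protein response, haematopoietic progenitor, neutrophil, dendritic cell, lymphocyte, erythroid, mast cell and basophil, fibroblast, osteoclast, mitochondrially encoded and ribosomal protein genes. Some lists share members, such as Fcgr1 and Mrc1, and Psmb9 had 0 counts in all libraries. Inducible genes (false discovery rate under 0.05 and log2 of 1 or more, averaged over genotypes) were compared with 10000 random lists matched on expression decile.

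Named genes followed a rule: the measured cohesin genes, 16 fixed genes, the largest called rises and falls per contrast with at least 2 CPM in the higher group, and up to 4 members per list with the smallest p. The text gives a subset of the genes the rule allows, and single-gene results for a few of them, 1 of the fixed genes included, are not reported here. Genes from the list and size parts whose call ended when 1 library was left out were passed over, a choice made after the values were seen.

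The replicate number was checked as a pairing. Over 135 pairs of same-numbered libraries from different groups, residuals from group means correlated at a mean r of 0.327 (0.0987 to 0.647), against -0.162 for differently numbered ones, and 30 of 30 libraries correlated best with their own number. 1 pair was at or under 0.1 (wild-type LPS 8 h and unstimulated Rad21-/-, replicate 1). The LPS 8 h difference and the mean of 5 use this pair, so their block values are given only where dependence on processing is described. Gene counts with the block had been seen in the same output before this choice was made.

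Alternatives were RLE factors, library totals, no low-count filter beyond 1 count, the replicate number as a block, a fit of the compared groups alone, DESeq2 1.42.0, leaving out each library in turn, fry in place of camera, and stricter or wild-type-only definitions of inducible genes. Added after the data were seen were camera without wild-type primed LPS 8 h replicate 2, splits balanced over genotype and splits of whole replicate sets.

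The fit was tested on simulated data with changes put into 100 of 14310 genes per contrast. Its false calls do not cover the correlation between same-numbered libraries. For the unstimulated genotype contrast it recovered 2 of 34 genes changed 1.5-fold, 18 of 33 changed 2-fold and 26 of 33 changed 4-fold, with 2 false calls. For the mean of 5 it recovered 24 of 34, 30 of 33 and 33 of 33, with 5 false calls, and for the LPS 8 h difference 0 of 33, 5 of 34 and 18 of 33, with 0. No recovered gene had the wrong direction. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.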

Results

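Total RNA was sequenced from mouse bone marrow-derived macrophages that were either wild-type or Rad21-/-, a line in which tamoxifen-inducible Cre removed Rad21, a subunit of the ring-shaped cohesin complex that holds sister chromatids and chromatin loops. Cells of each genotype were left unstimulated, exposed to lipopolysaccharide (LPS, a bacterial ligand of Toll-like receptor 4) for 2 h or 8 h, or primed with interferon-γ (IFN-γ) for 24 h and then exposed to LPS for 2 h or 8 h. Each of the 10 groups held 3 libraries, 30 in all, and no library received IFN-γ alone. Total counts per library ran from about 16016000 to 71224000, the smallest being wild-type primed LPS 8 h replicate 1, and the other 29 held at least 28215000. The labels do not say whether replicates were separate animals or cultures, though sex-linked genes set replicate 3 apart. Every p-value measures only the spread between libraries. In the principal component analysis, component 1 (41.3% of the variance of 2000 genes) mainly followed stimulation and component 2 (21.2%) mainly separated the genotypes.

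**Figure D1:**
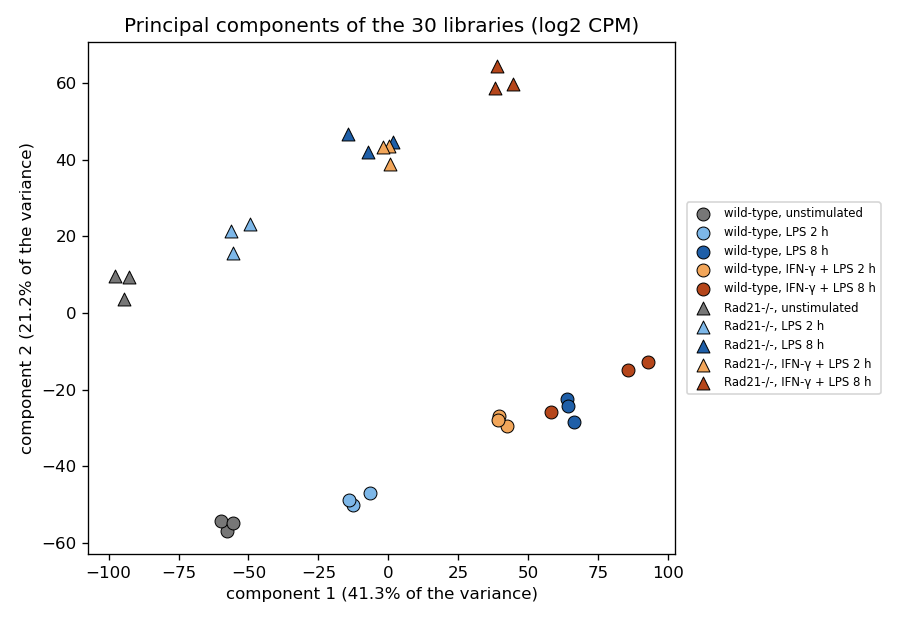
Principal components 1 and 2 of log2 CPM (counts scaled to library size) over the 2000 most variable genes, 1 point per library, circles for wild-type and triangles for Rad21-/-, colours for the 5 stimulations. The 15 Rad21-/- libraries lie above the 15 wild-type libraries on component 2, and wild-type primed LPS 8 h replicate 2 lies apart from the other libraries of its group.

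Rad21 itself, on chromosome 15 (51794151 to 51823306, mm9), was low in every library labelled Rad21-/-. Its level was 81.6 to 151 CPM in the 15 wild-type libraries and 3.66 to 8.45 CPM in the 15 Rad21-/- libraries. Group means in Rad21-/- were 4.26% (LPS 8 h) to 8.38% (primed LPS 2 h) of the wild-type mean at the same stimulation. Over the mean of the 5 stimulations Rad21 fell 18.9-fold (log2 -4.24 ± 0.09 SE). Counts of genes that overlap another annotated gene are uncertain, because the labels do not say whether counting used strand. Among the genes named here these are Angpt1, Angptl7, Ank2, Cd74, Cdc20, Cebpb, Cfb, Csf1r, Csf2, Ctcf, Cxcl10, Cxcl11, Ddit3, Dhx58, Ebi3, Egr1, Eif2ak2, Fcgr4, Fdft1, Foxm1, H2-Ab1, Hdac8, Herpud1, Hif1a, Icam1, Ifi47, Ifnar2, Il1a, Il1b, Irf5, Irf7, Lss, Maf, Mau2, Mrc1, mt-Nd1, mt-Nd2, Mvd, Pds5a, Pds5b, Pim1, Prc1, Ptges, Rpl3, Rpl5, Slc2a1, Smc1a and Stag1. Members of families with near-identical copies (the Ifi200, Gbp, Oas and H2 genes, ribosomal protein genes with pseudogenes) are uncertain too, since reads could have been split between copies.

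The choice of scaling moves the share of calls that are higher. Under library totals in place of TMM factors the median of all genes moved to log2 0.27 at LPS 2 h, 0.58 at LPS 8 h, 0.19 at primed LPS 2 h, 0.43 at primed LPS 8 h and 0.32 for the mean of the 5 genotype contrasts. In wild-type it moved to -0.39 for LPS 2 h and -0.64 for LPS 8 h against unstimulated, and in Rad21-/- to -0.23 and -0.16. The differences of those responses moved to 0.16 at 2 h and 0.48 at 8 h, and priming in Rad21-/- to -0.13 at 2 h and -0.20 at 8 h. Changes are reported relative to the TMM scale, and the share of called genes that were higher is given under both scales where it moved by more than 10 points.

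The first comparison asks how the genotypes differed before any stimulation. Interferon-responsive genes stood lower in unstimulated Rad21-/- macrophages (n = 3 per group). Irf7, a transcription factor that amplifies type I interferon production, fell 3.71-fold (log2 -1.89 ± 0.28 SE), the antiviral genes Ifit1 and Mx1 fell 4.85-fold (-2.28 ± 0.42) and 5.12-fold (-2.36 ± 0.55), and the chemokine gene Cxcl10 fell 6.76-fold (-2.76 ± 0.62). Of the 41 tested members of the type I interferon response list, 37 fell, 0 rose and 4 were not called, and 41 fell adjusted over the list alone (camera adjusted p = 1.1e-34, Oas3 -2.32 ± 0.18, Ifi204 -2.89 ± 0.27). With an estimated correlation the adjusted p = 0.085. The IFN-γ response list had 25 members lower, 1 higher and 9 not called of 35, with 27 lower and 1 higher adjusted over the list alone (adjusted p = 6.6e-16, and 0.14 with an estimated correlation). Among them were Cd274, which encodes the ligand PD-L1 (13.3-fold lower, -3.74 ± 0.40), Slamf8 (-3.73 ± 0.37) and Gbp6 (-2.65 ± 0.32). In the interferon signalling pathway list 6 of 20 members fell and 0 rose, 10 and 0 adjusted over the list alone, among them Irf5 (-0.85 ± 0.22; camera adjusted p = 0.014, and 0.33 with an estimated correlation).

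Macrophage identity genes had 10 members lower, 1 higher and 16 not called of 27 in the unstimulated cells, 13 lower and 1 higher adjusted over the list alone (camera adjusted p = 1.7e-04, and 0.33 with an estimated correlation). Fcgr1, an IgG receptor (-1.84 ± 0.25), Cebpb, a myeloid transcription factor (-1.79 ± 0.26), and C1qb, a complement subunit (-2.16 ± 0.39), fell, whereas Csf1r, the receptor for macrophage colony-stimulating factor, was not called (-0.22 ± 0.43, edgeR adjusted p = 0.83). Markers of another cell type moved alongside. Of 11 fibroblast markers 5 rose and 0 fell, 7 and 0 adjusted over the list alone (adjusted p = 0.0037, and 0.62 with an estimated correlation). Pdgfrb stood at 2.81 ± 0.72 CPM (SD, n = 3) against 0.35 ± 0.16 in wild-type (8.02-fold higher). Among 13 dendritic cell markers 3 rose and 1 fell, with the same counts adjusted over the list alone (adjusted p = 0.037, and 0.61 with an estimated correlation). They went both ways, as Cd209a rose (4.13 ± 0.67) and Batf3 fell (-3.84 ± 0.68). Mitochondrially encoded genes had 7 of 12 members higher and 0 lower, 8 and 0 adjusted over the list alone (adjusted p = 2.0e-05, and 0.33 with an estimated correlation). Members include mt-Nd2 (1.09 ± 0.24) and mt-Cytb (1.05 ± 0.26). In the integrated stress and unfolded protein response list 6 of 20 fell and 0 rose, 12 and 0 adjusted over the list alone (adjusted p = 0.0011, and 0.64 with an estimated correlation). Among these are Ddit3 (-1.72 ± 0.37) and Xbp1 (-0.78 ± 0.16).

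LPS response genes were mostly not called before stimulation. In the early LPS response list 4 members rose, 1 fell and 30 were not called of 35, with the same counts adjusted over the list alone. In the late list 1 rose, 5 fell and 20 were not called of 26, 1 and 6 adjusted over the list alone (camera adjusted p = 0.104 for the early and 0.149 for the late list). Tnf (0.42 ± 0.41), Il6 (-1.25 ± 1.48), Il1b (1.09 ± 0.58), Il12b (0.12 ± 0.94), Ifnb1 (-1.70 ± 3.17) and the cell cycle inhibitor gene Cdkn1a (0.01 ± 0.27) were not called. Nor was Il10 (0.93 ± 0.55), except in a fit of these 6 libraries alone (0.96). Lower already were Irg1, which makes itaconate (-3.19 ± 0.44), the chemokine gene Ccl5 (-2.01 ± 0.29) and Il1rn, the interleukin-1 receptor antagonist (-2.21 ± 0.34). Slamf7, a surface receptor, fell 106-fold (-6.72 ± 0.37). It lies within the same 3 Mb of chromosome 1 as Slamf1, Slamf8, Ifi204, Ifi205, Ifi202b and Pydc4, and 6 genes of that stretch were at least 8-fold apart between genotypes in all 5 stimulations. The cohesin gene Stag1 rose (0.84 ± 0.10). Stag2, its homologue, also rose (0.47 ± 0.14), but its call ended without the low-count filter (0.46) and without wild-type replicate 1 (0.41), wild-type replicate 3 (0.46), Rad21-/- replicate 2 (0.48) or Rad21-/- replicate 3 (0.39). In all, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment called 2167 of 14310 genes, 915 higher and 1252 lower (42.2% higher, and 56.0% under library totals).

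The next comparison asks which genes differed between genotypes 2 h into the LPS response. Of 7 cytokine and chemokine genes fixed beforehand, 4 stood lower in Rad21-/- cells and 3 were not called (n = 3 per group). Tnf fell 3.68-fold (-1.88 ± 0.42), Il6 fell 7.84-fold (-2.97 ± 0.70), Il10, an anti-inflammatory cytokine, fell 5.76-fold (-2.53 ± 0.57), and Il12b, a subunit of interleukins 12 and 23, fell 6.22-fold (-2.64 ± 0.72). Of 35 early LPS response genes 14 fell, 0 rose and 21 were not called, with 21 lower and 0 higher adjusted over the list alone (camera adjusted p = 1.9e-08, and 0.18 with an estimated correlation). Ptgs2, which encodes the prostaglandin enzyme cyclooxygenase-2 (-3.05 ± 0.37), the growth response factor gene Egr1 (-2.31 ± 0.41), Zfp36, which promotes decay of cytokine mRNA (-1.83 ± 0.32), and the kinase gene Pim1 (-2.13 ± 0.21) were among them. Of 26 late response genes 13 fell and 0 rose, 19 and 1 adjusted over the list alone (adjusted p = 1.5e-08, and 0.13 with an estimated correlation). Edn1, endothelin-1, fell 26.8-fold (-4.75 ± 0.54), and the collagenase gene Mmp13 (-4.36 ± 0.50), Il1rn (-2.08 ± 0.33) and Ccl5 (-1.62 ± 0.28) also fell. Ifnb1, interferon-β, was not called (-1.95 ± 1.14, edgeR adjusted p = 0.27), nor were Il1b (-1.17 ± 0.56) and Cxcl10 (-0.88 ± 0.58). Ifnb1 and Cxcl10 were called lower with the replicate number as a block (-2.31 and -1.03), Ifnb1 also without Rad21-/- replicate 1 (-4.03), and Il1b in a fit of these 6 libraries alone (-1.15). The call of Il12b ended without Rad21-/- LPS 2 h replicate 3 (-2.36).

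Interferon-responsive genes were lower at 2 h as well. Of the 41 type I genes 31 fell and 0 rose, 35 and 0 adjusted over the list alone (camera adjusted p = 5.3e-25, and 0.13 with an estimated correlation). They include Ifi205 (-3.68 ± 0.37), Oas3 (-2.46 ± 0.18) and Herc6 (-1.88 ± 0.19). Of 35 IFN-γ response genes 16 fell and 0 rose, 23 and 0 adjusted over the list alone (adjusted p = 6.3e-09, and 0.25 with an estimated correlation). Examples are Slamf8 (-3.26 ± 0.36) and Nlrc5 (-1.76 ± 0.22). In the signalling pathway list 7 fell and 1 rose of 20, 11 and 1 adjusted over the list alone (adjusted p = 0.0020, and 0.17 with an estimated correlation; Ifngr1, an IFN-γ receptor chain, -1.67 ± 0.40). Macrophage identity genes had 11 of 27 lower and 1 higher, 11 and 2 adjusted over the list alone (adjusted p = 2.5e-04, and 0.25 with an estimated correlation). Members include Cebpb (-2.83 ± 0.26). Of 20 stress response genes 6 fell and 0 rose, 9 and 0 adjusted over the list alone (adjusted p = 2.7e-04, and 0.61 with an estimated correlation). Beside these, 3 of 11 fibroblast markers rose and 0 fell, 5 and 0 adjusted over the list alone (adjusted p = 0.0069, and 0.61 with an estimated correlation). Of 13 dendritic cell markers 5 rose and 0 fell, also adjusted over the list alone (adjusted p = 0.015, and 0.40 with an estimated correlation). Among 12 mitochondrially encoded genes 1 rose and 0 fell, 0 and 0 adjusted over the list alone (adjusted p = 0.018, and 0.68 with an estimated correlation). The p53 targets went both ways, 3 up and 6 down of 27, 5 and 6 adjusted over the list alone. The list had a positive median (0.04) and a negative mean (-0.22) and was not called (adjusted p = 0.92). Sesn1 rose (3.16 ± 0.38), while Gdf15 (-3.64 ± 0.40) and Plk2 (-3.25 ± 0.41) fell. The quasi-likelihood test called 2671 genes, 1185 higher and 1486 lower (44.4% higher, and 73.6% under library totals).

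At 8 h of LPS the comparison asks the same of the late response. Nos2, inducible nitric oxide synthase, stood at 137 ± 157 CPM (SD, n = 3) in Rad21-/- cells and 3933 ± 1838 in wild-type, a 28.7-fold fall (-4.84 ± 0.74). Il10 fell 20.6-fold (-4.37 ± 0.62), the prostaglandin E synthase gene Ptges 21.7-fold (-4.44 ± 0.44) and Mmp13 43.1-fold (-5.43 ± 0.53). The late LPS response list had 17 of 26 members lower and 0 higher, also adjusted over the list alone (camera adjusted p = 2.1e-06, and 0.15 with an estimated correlation). Among these are Edn1 (-3.66 ± 0.51) and Il1rn (-2.62 ± 0.34). Of 35 early genes 19 fell and 0 rose, also adjusted over the list alone (adjusted p = 1.9e-04, and 0.45 with an estimated correlation). They include Zfp36 (-2.76 ± 0.33). Il6 fell (-2.14 ± 0.67), though not past the test without Rad21-/- LPS 8 h replicate 2 (-1.86). Il12b fell (-1.80 ± 0.70), but this call ended under library totals (-1.23) and without wild-type LPS 8 h replicate 1 (-1.50) or 3 (-1.80) or Rad21-/- LPS 8 h replicate 1 (-1.72), 2 (-1.99) or 3 (-1.69). Cxcl10 fell (-2.79 ± 0.61), and Tnf (-0.63 ± 0.41), Il1b (0.58 ± 0.55) and Ifnb1 (0.21 ± 1.24) were not called.

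**Figure D2:**
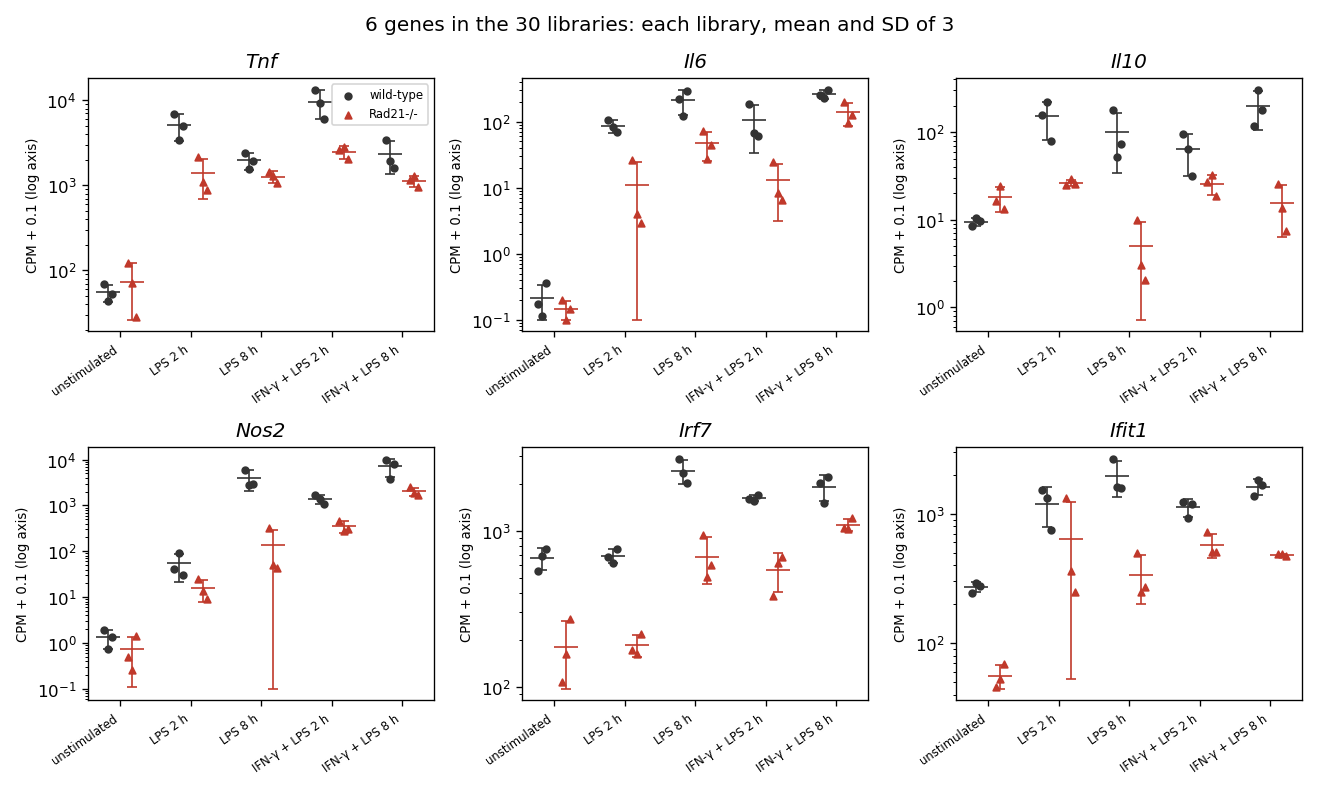
CPM of Tnf, Il6, Il10, Nos2, Irf7 and Ifit1 in each of the 30 libraries (log axis, 0.1 added), with the mean and SD of the 3 libraries per group as bars (drawn no lower than 0.1). For Nos2 the 3 Rad21-/- libraries at LPS 8 h lie below the 3 wild-type libraries, with means of 137 and 3933 CPM.

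All 41 tested type I interferon response genes fell at LPS 8 h, also adjusted over the list alone (camera adjusted p = 4.1e-21, and 0.15 with an estimated correlation). They include Stat2, a subunit of the interferon-activated transcription complex (-2.51 ± 0.25), the RNA-sensing kinase gene Eif2ak2 (-1.52 ± 0.16), Irf7 (-1.83 ± 0.28) and Ifit1 (-2.52 ± 0.42). Of 35 IFN-γ response genes 30 fell and 1 rose, 31 and 2 adjusted over the list alone (adjusted p = 8.0e-15, and 0.15 with an estimated correlation). Examples are Cd274 (-3.82 ± 0.40) and Nlrc5 (-2.46 ± 0.23). In the signalling pathway list 12 of 20 fell and 1 rose, also adjusted over the list alone (adjusted p = 0.0019, and 0.15 with an estimated correlation). Both chains of the type I interferon receptor were among the genes that fell (Ifnar1 -1.62 ± 0.19, Ifnar2 -2.25 ± 0.16), as were the kinase genes Jak2 (-1.74 ± 0.22) and Tbk1 (-1.15 ± 0.10). The glycolysis and hypoxia list had 16 of 22 members lower and 0 higher, 21 and 1 adjusted over the list alone (adjusted p = 2.1e-06, and 0.45 with an estimated correlation). Hif1a, the hypoxia-inducible factor, fell 3.96-fold (-1.99 ± 0.18), the glycolytic regulator Pfkfb3 18.6-fold (-4.22 ± 0.42), the glucose transporter gene Slc2a1 5.60-fold (-2.49 ± 0.35) and Bnip3 9.46-fold (-3.24 ± 0.41).

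Cholesterol synthesis genes went the other way at LPS 8 h, with 16 of 22 higher and 0 lower, 19 and 0 adjusted over the list alone (camera adjusted p = 5.7e-06, and 0.52 with an estimated correlation). Dhcr7, the last enzyme of the pathway, rose 10.2-fold (3.35 ± 0.41), and Mvd (1.67 ± 0.31) and Lss (1.57 ± 0.36), enzymes of earlier steps, also rose. Macrophage identity genes had 16 of 27 lower and 1 higher, 17 and 1 adjusted over the list alone (adjusted p = 7.7e-05, and 0.34 with an estimated correlation). Members include Fcgr3 (-2.36 ± 0.22) and Maf (-2.10 ± 0.25). Of 35 proliferation genes 11 rose and 2 fell, also adjusted over the list alone, and the list was not called (adjusted p = 0.16). The mitotic genes Cdc20 (3.03 ± 0.48) and Prc1 (2.39 ± 0.48) rose and Tpx2 fell (-1.84 ± 0.40). Fibroblast markers were higher beside these groups, 7 of 11 higher and 0 lower, also adjusted over the list alone (adjusted p = 0.085, and 0.030 with the replicate block). Col1a2 stood at 13.9 ± 8.4 CPM against 1.68 ± 0.29 (log2 3.04 ± 0.66), and Sparc rose (3.92 ± 0.77). Alternative activation genes had 5 of 12 lower and 1 higher, also adjusted over the list alone (adjusted p = 0.29; Il4ra -3.76 ± 0.46, Klf4 -2.17 ± 0.43, Pparg -2.39 ± 0.48). Arg1, arginase 1, had 132 counts in the 3 wild-type libraries and 0 in the 3 Rad21-/- libraries, at least 72.5-fold lower against a floor of 3 counts over the group. Cdkn1a fell (-1.71 ± 0.28), Lipg, endothelial lipase, fell 140-fold (-7.12 ± 0.79), and Chi3l1, a chitinase-like protein gene, rose 128-fold (7.00 ± 0.75). The test called 6427 genes, 3255 higher and 3172 lower (50.6% higher, and 81.1% under library totals).

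In primed cells at 2 h of LPS, 2 of the same 7 cytokine and chemokine genes stood lower in Rad21-/- macrophages, Tnf (3.86-fold, -1.95 ± 0.42) and Il6 (7.98-fold; n = 3 per group). Il12b (-0.53 ± 0.68), Il1b (0.32 ± 0.55) and Cxcl10 (-0.23 ± 0.57) were not called. Il10 (-1.30 ± 0.54) and Ifnb1 (-1.53 ± 1.13) were called only in some alternatives, both with the replicate block (-1.22 and -1.28) and Il10 in a fit of these 6 libraries alone (-1.31). Ptgs2 (9.08-fold, -3.18 ± 0.37) and Egr1 (4.77-fold, -2.25 ± 0.41) fell. Of 35 early genes 14 fell and 1 rose, also adjusted over the list alone (camera adjusted p = 0.0011, and 0.46 with an estimated correlation). In the late list 11 of 26 fell and 2 rose, 13 and 3 adjusted over the list alone (adjusted p = 0.0065, and 0.46 with an estimated correlation). Edn1 (-4.53 ± 0.54) and Ccl7 (-2.63 ± 0.53) fell and Ebi3, a subunit of interleukin 27, rose (1.10 ± 0.16). Nos2 fell (-1.97 ± 0.65), but not past the test without wild-type replicate 1 (-1.79) or Rad21-/- replicate 2 (-1.83) or 3 (-1.88). Type I interferon genes had 24 of 41 lower and 0 higher, 31 and 0 adjusted over the list alone (adjusted p = 2.0e-11, and 0.46 with an estimated correlation). Among these are Isg20 (-2.62 ± 0.39), Irf7 (-1.53 ± 0.27), Herc6 (-1.37 ± 0.19) and Ddx58 (-1.30 ± 0.19). The signalling pathway list had 4 of 20 lower and 0 higher, also adjusted over the list alone (adjusted p = 0.0999, and 0.044 with the replicate block). The IFN-γ response list was not called after priming, with 6 of 35 lower and 3 higher, 7 and 3 adjusted over the list alone (adjusted p = 0.32). Ubd rose (2.07 ± 0.39) and the complement gene Cfb fell (-1.90 ± 0.43).

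MHC class II genes, which present antigen to T cells, fell in the primed 2 h comparison, 6 of 10 lower and 0 higher, also adjusted over the list alone (camera adjusted p = 0.017, and 0.46 with an estimated correlation; H2-Ab1 3.37-fold, -1.75 ± 0.42, H2-DMb1 -1.55 ± 0.26, H2-Eb1 -1.53 ± 0.40). The stress response list had 12 of 20 lower and 0 higher, 15 and 0 adjusted over the list alone (adjusted p = 3.1e-06, and 0.46 with an estimated correlation). They include Ddit3 (-2.16 ± 0.38), Atf4 (-1.24 ± 0.26) and Herpud1 (-1.44 ± 0.23). Macrophage identity genes had 7 of 27 lower and 1 higher, 8 and 1 adjusted over the list alone (adjusted p = 0.017, and 0.50 with an estimated correlation). Examples are Cebpb (-2.53 ± 0.26) and C1qa (-1.42 ± 0.25). Ribosomal protein genes had 11 of 45 higher and 1 lower, also adjusted over the list alone (adjusted p = 1.6e-05, and 0.61 with an estimated correlation). Members include Rpl3 (0.90 ± 0.16) and Rpl14 (0.71 ± 0.17). Of 12 mitochondrially encoded genes 7 rose and 0 fell, 8 and 0 adjusted over the list alone (adjusted p = 2.2e-04, and 0.46 with an estimated correlation). Among these are mt-Nd2 (1.23 ± 0.24) and mt-Nd1 (1.23 ± 0.26). The test called 3389 genes, 1604 higher and 1785 lower (47.3% higher, and 69.3% under library totals).

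In primed cells at 8 h, early LPS response genes gave the highest count of lower members among the 5 genotype contrasts. Of 35 members 27 fell and 0 rose, 29 and 0 adjusted over the list alone (camera adjusted p = 1.4e-08, and 0.28 with an estimated correlation). The chemokine gene Ccl3 fell 7.31-fold (-2.87 ± 0.35), Ptgs2 7.63-fold (-2.93 ± 0.37), Ier3 4.60-fold (-2.20 ± 0.22) and Pim1 4.32-fold (-2.11 ± 0.21). Of 26 late genes 16 fell and 1 rose, also adjusted over the list alone (adjusted p = 8.4e-05, and 0.28 with an estimated correlation). They include Csf3, granulocyte colony-stimulating factor (30.7-fold, -4.94 ± 0.66), Il10 (13.1-fold, -3.71 ± 0.60), Ptges (-3.87 ± 0.43), Edn1 (-3.94 ± 0.52) and Mmp13 (-3.52 ± 0.48). Wild-type replicate 2 lies apart in components 1 and 2. It held 13 genes picked as high at LPS 2 h at a median share of 0.535 of that level. Without it 20 early genes fell and 0 rose, 15 late genes fell and 1 rose, and the contrast called 5965 genes. Of the 5947 genes called with it 5089 were called again and 35 had the opposite sign. Tnf fell (-1.05 ± 0.41), yet its call ended under library totals (-0.57) and without wild-type replicate 1 (-0.72) or Rad21-/- replicate 1 (-1.05), 2 (-1.15) or 3 (-0.93). Nos2 fell (-1.84 ± 0.65), and its call ended under library totals (-1.37) and without wild-type replicate 1 (-1.59) or 3 (-1.77) or Rad21-/- replicate 2 (-1.78) or 3 (-1.73). Il12b (-0.63 ± 0.68), Il1b (-0.46 ± 0.55) and Cxcl10 (-0.58 ± 0.58) were not called. Nor were Il6 (-0.90 ± 0.65) and Ifnb1 (-2.74 ± 1.23), except in a fit of these 6 libraries alone (-0.93 and -2.76) and, for Ifnb1, with the replicate block and by DESeq2.

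Type I interferon genes had 24 of 41 lower and 0 higher in the primed 8 h comparison, 26 and 0 adjusted over the list alone (camera adjusted p = 1.7e-06, and 0.70 with an estimated correlation). The count was 25 lower without wild-type replicate 2. The IFN-γ response list was not called, with 3 of 35 lower and 1 higher, also adjusted over the list alone (adjusted p = 0.63), and 5 lower and 1 higher without replicate 2 (adjusted p = 0.22). Oas2 (-1.29 ± 0.20) and Mx1 (-1.77 ± 0.53) fell. Irf7 fell (-0.81 ± 0.27), but not past the test under library totals (-0.36) or without wild-type replicate 3 (-0.68) or Rad21-/- replicate 1 (-0.77) or 2 (-0.76). The signalling list had 9 of 20 lower and 0 higher, also adjusted over the list alone (adjusted p = 0.0043, and 0.28 with an estimated correlation). They include Ifnar1 (-1.64 ± 0.19) and Ifnar2 (-0.98 ± 0.15). Without replicate 2 the counts were 7 lower and 1 higher. Macrophage identity genes had 16 of 27 lower and 0 higher, 17 and 1 adjusted over the list alone (adjusted p = 8.4e-05, and 0.28 with an estimated correlation). Mrc1, the mannose receptor (-3.57 ± 0.48), and Cebpb (-2.81 ± 0.26) fell. Without that library the counts were 12 lower and 2 higher. The glycolysis and hypoxia list had 7 of 22 lower and 0 higher, also adjusted over the list alone (adjusted p = 0.0013, and 0.88 with an estimated correlation). Hif1a (-1.55 ± 0.17), Pfkfb3 (-3.66 ± 0.41) and the angiogenic factor gene Vegfa (-4.18 ± 0.69) fell. Without replicate 2 the count was 8 lower. Cholesterol synthesis genes had 2 higher and 1 lower of 22, 1 and 0 adjusted over the list alone, and were not called (adjusted p = 0.42), whereas without replicate 2 the counts were 9 higher and 0 lower (camera adjusted p = 0.020). MHC class II genes had 5 lower and 1 higher of 10, also adjusted over the list alone (adjusted p = 0.43), and 2 lower and 0 higher without replicate 2; H2-Ab1 fell (-1.65 ± 0.42).

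Other genes named in the primed 8 h comparison were Gdf15 (-4.04 ± 0.41), Cdkn1a (-1.96 ± 0.28) and the proliferation marker Mki67 (-3.18 ± 0.45), all lower in Rad21-/- cells. F2rl1, a protease-activated receptor gene, had 212 counts in wild-type and 0 in Rad21-/-, at least 97.0-fold lower against a floor of 3 counts over the group. Arg1 had 45 counts against 0, at least 20.6-fold lower, but this bound rests on wild-type replicate 3, which holds 43 of the 45. Its call ended without that library, where 2 counts face 0 and no fold can be given. The test called 5947 genes, 2956 higher and 2991 lower (49.7% higher, and 78.0% under library totals). A fit of these 6 libraries alone called 3666.

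**Figure D3:**
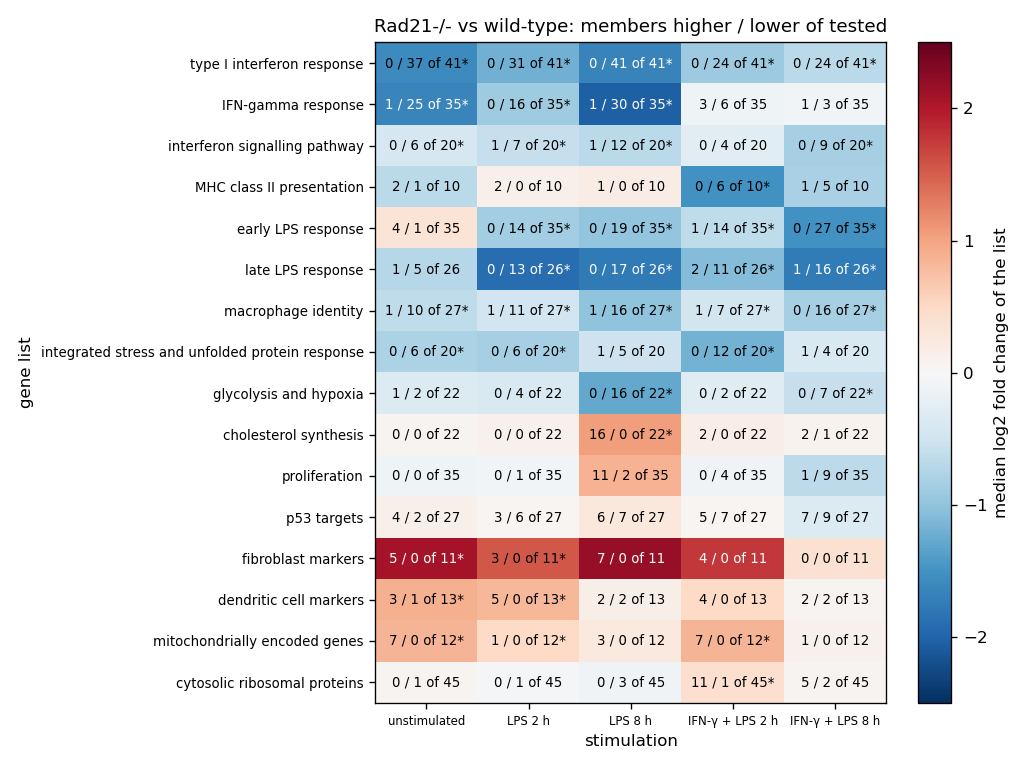
Median log2 fold change (Rad21-/- against wild-type) of 16 gene lists at the 5 stimulations, 3 libraries per group. Numbers are members called higher and lower of those tested, an asterisk marks a camera adjusted p below 0.05 with the preset correlation, and the type I interferon row runs from 24 to 41 lower of 41.

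Averaged over the 5 stimulations, the genotype difference went in both directions. The test called 8554 of 14310, 4286 higher and 4268 lower (50.1% higher, and 76.9% under library totals). Among the genes fixed beforehand, Nos2 (-2.31 ± 0.30), Il10 (-2.20 ± 0.25), Il6 (-2.05 ± 0.40), Mx1 (-1.85 ± 0.24), Ifit1 (-1.68 ± 0.18), Irf7 (-1.59 ± 0.12), Cxcl10 (-1.45 ± 0.26), Il12b (-1.09 ± 0.33), Tnf (-1.02 ± 0.18) and Cdkn1a (-0.99 ± 0.12) fell. Arg1 was called lower too, but no fold is given because Rad21-/- cells had 0 counts of it at LPS 8 h with and without priming. Il1b (0.07 ± 0.25), Ifnb1 (-1.54 ± 0.79), Csf1r (-0.32 ± 0.19) and Myc (0.11 ± 0.29) were not called. Ifnb1 was called lower by DESeq2 and without Rad21-/- LPS 2 h replicate 1 (-1.96) or primed LPS 2 h replicate 1 (-1.82), and Csf1r without wild-type primed LPS 8 h replicate 1 (-0.41). Calls in all 5 stimulations were shared by 745 genes, of which 278 were higher in each and 458 lower in each. The larger folds included Npy, neuropeptide Y (1041-fold lower, -10.02 ± 0.28), Pydc4 (-6.79 ± 0.23), Gpr162 (-6.45 ± 0.39), Lipg (-6.29 ± 0.36), Gdpd1 (-4.74 ± 0.20) and Flt1, a VEGF receptor (-4.56 ± 0.20). On the other side were Ifi202b (2327-fold higher, 11.18 ± 0.24), Angptl7 (6.79 ± 0.28), Clrn3 (6.42 ± 0.44) and Pvrl3 (6.22 ± 0.21).

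Cohesin genes other than Rad21 moved by less than 0.7 log2 over the mean of the 5 stimulations. Of the 15 members of the list 7 rose and 3 fell, also adjusted over the list alone, and the list was not called (camera adjusted p = 0.40), with a positive median (0.15) and a negative mean (-0.13). The subunit genes Smc3 (0.39 ± 0.05), Stag1 (0.62 ± 0.04) and Stag2 (0.33 ± 0.06), the regulators Pds5a (0.37 ± 0.06) and Hdac8 (0.31 ± 0.07), and Ctcf, the loop boundary factor (0.20 ± 0.06), rose. Pds5b rose too (0.23 ± 0.09), though its call ended without any 1 of 11 libraries (0.19 to 0.22). In wild-type these were unstimulated replicates 2 and 3, replicate 3 at LPS 2 h, LPS 8 h and primed LPS 2 h, and primed LPS 8 h replicates 1 and 3. In Rad21-/- they were replicate 1 unstimulated, at LPS 2 h and at primed LPS 2 h and 8 h. Smc1a (-0.31 ± 0.07) and Mau2 (-0.22 ± 0.06) fell on the TMM scale and changed sign under library totals (0.01 and 0.11). Nipbl (0.15 ± 0.09), Wapal (-0.11 ± 0.05), Esco1 (0.15 ± 0.07), Esco2 (0.02 ± 0.35) and Cdca5 (0.15 ± 0.20) were not called, and Wapal also changed sign under library totals (0.21). Nipbl was called without wild-type LPS 2 h replicate 2 (0.21) or primed LPS 2 h replicate 2 (0.20), and under library totals, as were Esco1 and Cdca5. Wapal was called lower by DESeq2 and without wild-type replicate 1 at any LPS stimulation (-0.14 to -0.12). Esco1 was called without wild-type LPS 2 h replicate 3, LPS 8 h replicate 2, primed LPS 2 h replicate 3 or primed LPS 8 h replicate 3 (0.18 in each).

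Over the mean of the 5 stimulations the type I interferon response list fell with 41 of 41 lower (camera adjusted p = 4.8e-21, and 0.23 with an estimated correlation). The other lists follow with the same pair of adjusted p-values in brackets. IFN-γ response fell with 31 lower and 2 higher of 35 (4.8e-09 and 0.25). Early LPS response fell with 26 and 1 of 35 (1.9e-05 and 0.33) and late LPS response fell with 19 and 2 of 26 (5.1e-05 and 0.25). Macrophage identity fell with 21 and 1 of 27 (1.9e-05 and 0.25) and interferon signalling with 14 and 1 of 20 (6.4e-04 and 0.23). Glycolysis and hypoxia fell with 16 and 1 of 22 (3.8e-04 and 0.62) and stress and unfolded protein response with 16 and 1 of 20 (6.4e-04 and 0.62). Mitochondrially encoded genes rose with 10 higher and 0 lower of 12 (0.0021 and 0.62). Cholesterol synthesis rose with 8 and 0 of 22 (0.0099 and 0.62) and fibroblast markers with 8 and 0 of 11 (0.025 and 0.62). Without wild-type primed LPS 8 h replicate 2 the counts were 15 higher and 0 lower for cholesterol synthesis, 25 lower and 2 higher for early LPS response and 41 lower for type I interferon response.

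Lists not called over the mean of the 5 stimulations, given as higher and lower of those tested, were MHC class II presentation with 2 and 6 of 10 (camera adjusted p = 0.55), alternative activation with 3 and 7 of 12 (0.26), proliferation with 2 and 8 of 35 (0.72) and p53 targets with 10 and 10 of 27 (0.94). The same holds for haematopoietic progenitor with 5 and 4 of 12 (0.46), neutrophil with 1 and 2 of 12 (0.72), dendritic cell with 8 and 3 of 13 (0.26) and lymphocyte with 1 and 3 of 5 (0.46). It holds for erythroid with 1 and 0 of 3 (0.62), osteoclast with 2 and 3 of 7 (0.46) and cytosolic ribosomal proteins with 8 and 3 of 45 (0.26). Mast cell and basophil markers had 1 tested member and no test. Adjusted over the list alone, the counts changed for MHC class II presentation (3 higher and 6 lower), proliferation (2 and 6), glycolysis and hypoxia (1 and 17) and ribosomal proteins (7 and 3), and stayed the same for the other lists tested. For p53 targets the median (0.02) and the mean (-0.21) differ in sign, as they do for erythroid markers (-0.04 and 0.39).

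The next comparisons ask what LPS did in wild-type cells. At 2 h, Tnf rose 92.3-fold (6.53 ± 0.52; n = 3 per group), Il1b 688-fold (9.43 ± 0.80), Il6 690-fold (9.43 ± 1.00), Il12b 1437-fold (10.49 ± 1.05), Il1a 943-fold (9.88 ± 0.89), Edn1 1597-fold (10.64 ± 0.76) and Ifnb1 771-fold (9.59 ± 1.77). Csf2, a myeloid growth factor gene, and Sele, E-selectin, had 0 counts before LPS and rose at least 892-fold and 277-fold against a floor of 3 counts over the group. Of 35 early genes 33 rose and 0 fell, 33 and 1 adjusted over the list alone. Of 26 late genes 24 rose and 0 fell, 25 and 0 adjusted over the list alone (camera adjusted p = 4.1e-39 for early and 2.2e-23 for late genes, and adjusted p = 0.0010 for both with an estimated correlation). Ptgs2 (7.59 ± 0.46), the adhesion gene Icam1 (4.36 ± 0.26), Nfkbie (3.53 ± 0.18), Cd40 (4.14 ± 0.22), Ccl5 (4.96 ± 0.32), Nos2 (5.46 ± 0.78), Il10 (4.01 ± 0.61) and Cdkn1a (2.79 ± 0.29) rose. In the signalling list 11 of 20 rose and 0 fell, 12 and 0 adjusted over the list alone (adjusted p = 3.1e-05, and 0.027 with an estimated correlation). Examples are Jak2 (2.64 ± 0.22) and Socs1 (4.35 ± 0.60). Type I interferon genes had 15 of 41 higher and 0 lower at 2 h, 16 and 1 adjusted over the list alone (adjusted p = 1.1e-05, and 0.91 with an estimated correlation). Cxcl10 (5.60 ± 0.70) and Ifi205 (4.49 ± 0.39) rose and Irf7 (0.04 ± 0.27) was not called. The IFN-γ response list had 12 of 35 higher and 0 lower, 13 and 0 adjusted over the list alone (adjusted p = 1.7e-04, and 0.91 with an estimated correlation). Bmf (-5.00 ± 0.56), Cbx8 (-4.54 ± 0.40) and the myeloid factor gene Cebpa (-2.17 ± 0.32) fell. The test called 3660 genes, 1896 higher and 1764 lower (51.8% higher, and 20.8% under library totals).

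By 8 h of LPS the interferon-responsive lists had risen in wild-type cells, with 40 of 41 type I genes higher and 0 lower and 32 of 35 IFN-γ response genes higher and 1 lower, also adjusted over the list alone (camera adjusted p = 2.5e-16 and 3.6e-14, and adjusted p = 0.18 and 0.11 with an estimated correlation). Ifi205 (7.11 ± 0.43), Irf7 (1.86 ± 0.28), Gbp5 (6.37 ± 0.34) and Gbp2 (4.69 ± 0.29) rose. All 26 late genes rose, also adjusted over the list alone (adjusted p = 6.0e-17, and 0.0092 with an estimated correlation). Nos2 rose 3147-fold (11.62 ± 0.99), Lcn2, an iron-sequestering protein gene, 2348-fold (11.20 ± 0.61), Edn1 (11.73 ± 0.78) and Csf2 at least 595-fold against its 0 counts. Of 35 early genes 30 rose and 2 fell, also adjusted over the list alone (adjusted p = 1.8e-14, and 0.067 with an estimated correlation). Members include Ptgs2 (9.82 ± 0.50), Tnfaip3 (5.32 ± 0.33) and Tnf (5.16 ± 0.48). Slamf1 (12.97 ± 1.08), Il19 (11.89 ± 1.02) and Steap4 (11.53 ± 1.30) also rose. Glycolysis and hypoxia genes had 13 of 22 higher and 1 lower, 15 and 2 adjusted over the list alone (adjusted p = 2.7e-04, and 0.92 with an estimated correlation). Among these are Hif1a (3.32 ± 0.19), Pfkfb3 (5.50 ± 0.45) and Slc2a1 (3.99 ± 0.37). Proliferation genes had 28 of 35 lower and 1 higher, 29 and 2 adjusted over the list alone (adjusted p = 4.6e-06, and 0.92 with an estimated correlation). Cdc20 (-3.95 ± 0.49), Foxm1 (-3.63 ± 0.49) and the replication gene Mcm2 (-3.07 ± 0.43) fell. The cohesin acetyltransferase gene Esco2 fell with them (-4.54 ± 0.71). The test called 7882 genes, 3771 higher and 4111 lower (47.8% higher, and 21.8% under library totals).

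Rad21-/- cells responded to LPS as well. At 2 h, 28 of 35 early genes rose and 2 fell, 30 and 3 adjusted over the list alone. Of 26 late genes 22 rose and 0 fell, also adjusted over the list alone (camera adjusted p = 4.0e-29 for early and 5.5e-19 for late genes, and adjusted p = 0.0028 for both with an estimated correlation). At 8 h, 25 late genes rose and 1 fell, also adjusted over the list alone (adjusted p = 6.4e-16, and 0.013 with an estimated correlation). Of 41 type I interferon genes 39 rose and 0 fell, 40 and 0 adjusted over the list alone (adjusted p = 1.7e-17, and 0.14 with an estimated correlation). The test called 2639 genes at 2 h, 1488 higher and 1151 lower (56.4% higher, and 32.5% under library totals), and 6072 at 8 h, 3177 higher and 2895 lower (52.3% higher, and 37.5% under library totals). Across genes, which are not independent replicates, the response in Rad21-/- correlated with that in wild-type at r = 0.81 at 2 h and 0.76 at 8 h. Of the 4607 genes called in both genotypes at 8 h 4440 had the same direction.

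Whether the LPS response itself differed between genotypes was tested by the difference of the responses. At 2 h, early LPS response genes rose less in Rad21-/- cells, with a list median of -1.32. Of 35 members 5 were lower and 0 higher, and 20 and 0 adjusted over the list alone (camera adjusted p = 2.4e-31, and 0.0033 with an estimated correlation). Ptgs2 (-3.73 ± 0.51), Ccl3 (-2.70 ± 0.46) and Egr1 (-3.06 ± 0.57) had lower responses, Tnf missed the threshold (-2.30 ± 0.58, edgeR adjusted p = 0.091) but was called with the replicate block, by DESeq2 and without Rad21-/- unstimulated replicate 3 (-2.67) or LPS 2 h replicate 1 (-2.78), and Plat, tissue plasminogen activator, differed by -6.30 ± 0.88. Slamf7 had a higher response (3.56 ± 0.42). Il10 had a lower response (-3.45 ± 0.78). Its call ended without any 1 of the 12 libraries (-3.52 to -3.08) except wild-type LPS 2 h replicate 3 and Rad21-/- unstimulated replicate 3. Of 26 late genes 3 were lower and 0 higher, 5 and 1 adjusted over the list alone (adjusted p = 5.3e-04, and 0.58 with an estimated correlation). The test called 55 genes, 18 higher and 37 lower (32.7% higher, 48.5% under library totals and 45.5% by DESeq2). The count was 137 with the replicate block and 145 by DESeq2. It fell to 25 without wild-type unstimulated replicate 2, 36 without replicate 3, 31 without wild-type LPS 2 h replicate 1, 32 without Rad21-/- unstimulated replicate 1, 23 without replicate 2, and 34 or 29 without Rad21-/- LPS 2 h replicate 2 or 3.

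At 8 h the difference of the LPS responses reached 2425 genes, 1272 higher and 1153 lower in Rad21-/- (52.5% higher, and 84.6% of 4045 under library totals). Early genes had 14 of 35 lower responses and 0 higher, 19 and 0 adjusted over the list alone (camera adjusted p = 7.0e-08, and 0.73 with an estimated correlation). They include Ptgs2 (-3.67 ± 0.51), Ier3 (-1.99 ± 0.30), Zfp36 (-2.86 ± 0.45) and Dusp2 (-3.68 ± 0.61). Late genes had 5 of 26 lower and 1 higher, 8 and 1 adjusted over the list alone (adjusted p = 0.013, and 0.77 with an estimated correlation). Examples are Il10 (-5.29 ± 0.81) and Ptges (-4.29 ± 0.61). Nos2 differed by -3.78 ± 1.00, a call that ended in a fit of these 4 groups alone (-3.79) and without Rad21-/- unstimulated replicate 3 (-2.73). The glycolysis and hypoxia list had 5 of 22 lower and 0 higher, also adjusted over the list alone (adjusted p = 1.9e-05, and 0.77 with an estimated correlation). Members include Hif1a (-2.55 ± 0.24) and Pfkfb3 (-4.51 ± 0.55). Cholesterol synthesis had 5 of 22 higher and 0 lower, also adjusted over the list alone (adjusted p = 1.0e-05, and 0.77 with an estimated correlation). Among these are Dhcr7 (2.71 ± 0.53) and Mvk (1.42 ± 0.37). The response of Ifnar2 (-1.76 ± 0.21), Cdkn1a (-1.72 ± 0.39), Slamf1 (-6.08 ± 1.26) and Fst, follistatin (-6.16 ± 1.19), was lower, and that of Bmp2 (6.52 ± 0.98) and Ednrb (4.89 ± 0.84) higher. The type I interferon list was not called in this difference, with 1 of 41 higher and 1 lower, also adjusted over the list alone (adjusted p = 0.19).

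The share of LPS-inducible genes lower in Rad21-/- was compared with that of other genes. Inducible genes were those that rose at least 2-fold on the average of both genotypes, a contrast independent of the genotype difference in a balanced design. At 2 h, 29.5% of 1103 inducible genes were lower in Rad21-/- against a mean of 11.2% in 10000 random lists matched on expression (2-sided permutation p = 2.0e-04, the smallest these lists can give), and 7.25% were higher against 7.98% (permutation p = 0.38). At 8 h, 52.6% of 1952 inducible genes were lower against 20.2%, and 10.2% were higher against 21.1% (both 2-sided permutation p = 2.0e-04, again the smallest possible). The median log2 difference was -0.50 for inducible genes and 0.01 for others at 2 h, and -0.89 and 0.11 at 8 h. By camera the sets were lower with p = 5.0e-08 and 7.7e-19, and p = 0.052 and 5.5e-05 with an estimated correlation.

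**Figure D4:**
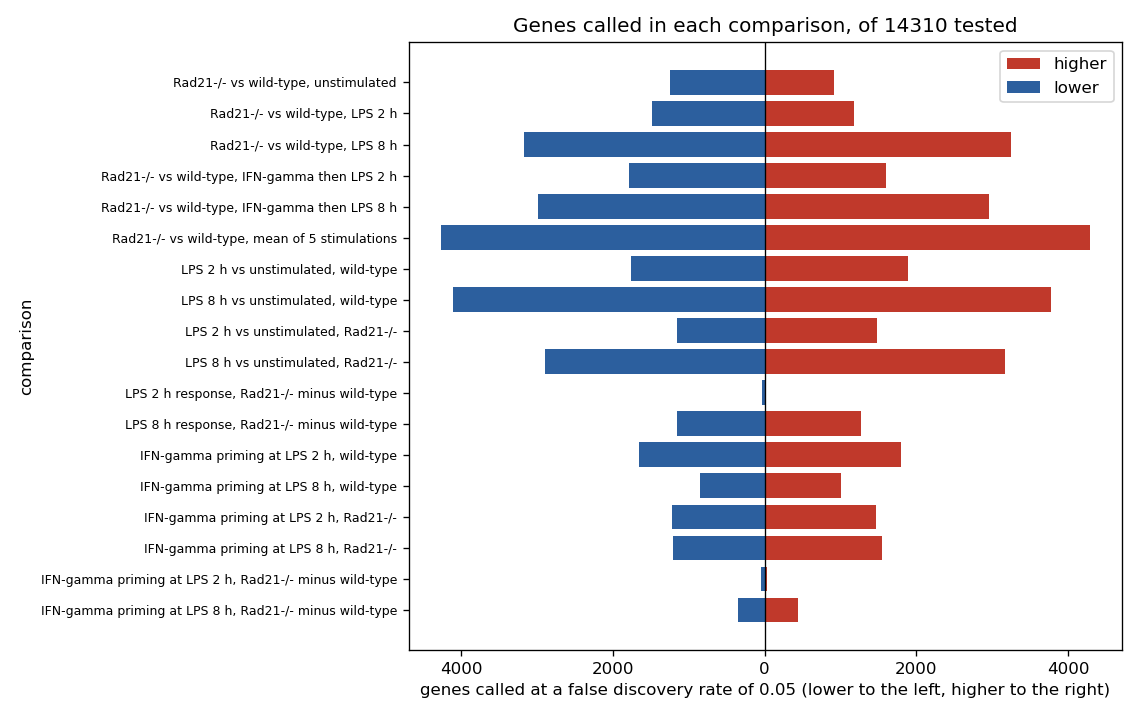
Genes called at a false discovery rate of 0.05 in each of the 18 comparisons, of 14310 tested, with higher genes drawn to the right and lower genes to the left. Counts run from 55 for the LPS 2 h interaction to 8554 for the mean genotype difference.

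Priming was examined by comparing primed with unprimed cells at the same time of LPS. In wild-type cells at 2 h, all 35 IFN-γ response genes and all 10 MHC class II genes rose, also adjusted over the list alone (camera adjusted p = 8.7e-40 and 5.8e-16, and adjusted p = 0.0065 and 0.0080 with an estimated correlation; n = 3 per group). The guanylate-binding protein gene Gbp10 rose 1342-fold (10.39 ± 0.44), Gbp4 204-fold (7.67 ± 0.53), Tlr12 1071-fold (10.06 ± 0.66), Nos2 (4.64 ± 0.73), H2-DMa (3.71 ± 0.33) and Cd74, the class II invariant chain (4.27 ± 0.46), rose. Tnf (0.91 ± 0.41) and Il6 (0.28 ± 0.64) were not called, though Tnf was with the replicate block (0.87). Type I interferon genes had 19 of 41 higher and 0 lower, 21 and 0 adjusted over the list alone (adjusted p = 1.0e-07, and 0.51 with an estimated correlation). Cholesterol synthesis genes had 15 of 22 lower and 0 higher, 18 and 0 adjusted over the list alone (adjusted p = 2.7e-07, and 0.51 with an estimated correlation). They include Fdft1 (-1.91 ± 0.35) and Sqle (-2.37 ± 0.50). Mitochondrially encoded genes had 8 of 12 lower and 0 higher, 9 and 0 adjusted over the list alone (adjusted p = 1.3e-06, and 0.31 with an estimated correlation). Examples are mt-Nd2 (-1.56 ± 0.25). Ribosomal protein genes had 12 of 45 lower and 0 higher, 18 and 0 adjusted over the list alone (adjusted p = 9.9e-07, and 0.54 with an estimated correlation). Members include Rpl5 (-0.72 ± 0.17). Csf2 (-5.54 ± 0.79), the neutrophil chemokine gene Cxcl3 (-5.37 ± 0.75), Il19 (-5.06 ± 0.95) and Myc (-3.65 ± 0.70) fell. The test called 3460 genes, 1802 higher and 1658 lower.

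At 8 h of LPS, priming in wild-type cells left all 10 MHC class II genes higher, also adjusted over the list alone (camera adjusted p = 2.0e-18, and 0.0072 with an estimated correlation). Among these are H2-DMb1 (2.76 ± 0.28) and Cd74 (3.81 ± 0.45). Of 35 IFN-γ response genes 14 were higher and 1 lower, 18 and 3 adjusted over the list alone (adjusted p = 1.3e-09, and 0.56 with an estimated correlation). They include Ubd (8.27 ± 0.67) and Gbp4 (4.20 ± 0.45). Gbp10 (7.53 ± 0.37) and Cdkn1a (1.27 ± 0.28) rose, Nos2 was not called (0.87 ± 0.63), and Itgb8 (-3.89 ± 0.42), Dgat2 (-3.49 ± 0.45) and Angpt1 (-4.24 ± 0.67) fell. Cholesterol synthesis genes had 9 of 22 lower and 0 higher, 11 and 0 adjusted over the list alone (adjusted p = 4.7e-07, and 0.85 with an estimated correlation). Fdft1 (-1.81 ± 0.35) and Ddx58 (-0.82 ± 0.19) fell, but neither was called in a fit of the 6 libraries alone (-1.79 and -0.80). Without the doubted replicate 2 the counts were 10 of 10 for MHC class II, 18 higher and 1 lower for IFN-γ response and 18 lower for cholesterol synthesis. The test called 1859 genes, 1001 higher and 858 lower. With the replicate number as a block it called 2956, without the doubted library 2594 (1084 higher and 1510 lower, 41.8% higher, with 1520 of the 1859 called again), without wild-type primed replicate 1 1266 (883 higher and 383 lower, 69.7% higher), without wild-type LPS 8 h replicate 1 2624 (45.2% higher), without wild-type LPS 8 h replicate 2 or 3 1059 or 1194, and in a fit of the 6 libraries alone 214, of which 85.0% were higher against 53.8%.

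Rad21-/- cells primed in the same way raised IFN-γ response genes at both times, with 34 of 35 higher and 0 lower at 2 h, 35 and 0 adjusted over the list alone. At 8 h 32 were higher and 0 lower, also adjusted over the list alone (camera adjusted p = 1.4e-51 at 2 h and 8.3e-39 at 8 h, and adjusted p = 0.0015 and 0.0073 with an estimated correlation). MHC class II genes had 9 of 10 higher and 0 lower at each time, also adjusted over the list alone (adjusted p = 4.5e-10 and 7.7e-10, and adjusted p = 0.055 and 0.070 with an estimated correlation). Cholesterol synthesis genes had 10 of 22 lower and 0 higher at 2 h, 12 and 0 adjusted over the list alone. At 8 h 21 were lower and 0 higher, also adjusted over the list alone (adjusted p = 4.8e-06 at 2 h and 2.8e-16 at 8 h, and adjusted p = 0.44 and 0.15 with an estimated correlation). The test called 2694 genes at 2 h, 1469 higher and 1225 lower (54.5% higher, and 42.2% under library totals), and 2750 at 8 h, 1547 higher and 1203 lower (56.3% higher, and 41.9% under library totals). Across genes the priming effects of the genotypes correlated at r = 0.74 at 2 h and 0.45 at 8 h.

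The difference in priming between genotypes was small in gene number at 2 h, 36 genes higher and 43 lower, 79 in all (45.6% higher). IFN-γ response genes had 4 of 35 members with a stronger priming effect in Rad21-/- and 0 weaker, 10 and 0 adjusted over the list alone (camera adjusted p = 3.2e-09, and 0.57 with an estimated correlation). They include Fcgr4, an IgG receptor (2.48 ± 0.40). MHC class II genes leaned the other way, with 0 of 10 called and 7 lower adjusted over the list alone (median -1.69, adjusted p = 1.2e-08, and 0.17 with an estimated correlation). Ank2 differed by 4.96 ± 0.55, Cnn3 by -4.80 ± 0.76 and Kynu, an enzyme of tryptophan breakdown, by -3.51 ± 0.63. The count was 329 with the replicate block, 254 by DESeq2 and 167 in a fit of the 12 libraries alone (104 higher and 63 lower, 62.3% higher). Leaving out 1 library gave 49 (wild-type LPS 2 h replicate 1), 45 or 51 (Rad21-/- LPS 2 h replicate 2 or 3), 142 or 51 (wild-type primed replicate 2 or 3) and 46, 36 or 46 (Rad21-/- primed replicate 1, 2 or 3).

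At 8 h, 26 of 35 IFN-γ response genes had a stronger priming effect in Rad21-/- cells and 0 a weaker one, 30 and 0 adjusted over the list alone (median 1.84, camera adjusted p = 5.2e-30, and 0.019 with an estimated correlation). Fcgr4 (3.29 ± 0.41), Nlrc5, a regulator of class I MHC genes (2.19 ± 0.31), and Ifi47 (2.17 ± 0.32) were among them. Type I interferon genes had 16 of 41 higher and 0 lower, 25 and 0 adjusted over the list alone (adjusted p = 1.3e-19, and 0.27 with an estimated correlation). Dhx58 (1.30 ± 0.24), Eif2ak2 (1.23 ± 0.23) and Cxcl11 (4.43 ± 1.05) differed, but were not called in a fit of the 4 groups alone (1.25, 1.19 and 4.37). Nor were the mitotic gene Cenpa (-4.12 ± 0.85, and -4.13 alone) and Mvd (-2.09 ± 0.44, and -2.12 alone). Proliferation genes had 7 of 35 lower and 0 higher, 17 and 1 adjusted over the list alone (adjusted p = 1.4e-06, and 0.73 with an estimated correlation). Ank2 (5.40 ± 0.57), Lpin1 (-5.23 ± 0.63) and S1pr3 (-5.17 ± 0.99) gave the larger single differences. Without the doubted wild-type replicate 2 the counts were 22 higher for IFN-γ response, 11 higher for type I interferon and 1 lower for proliferation, and 617 genes were called, 442 higher and 175 lower (71.6% higher), 487 of them among the 785 called with it. Without wild-type primed replicate 1 the balance turned, with 418 higher and 536 lower (43.8% higher). The test called 785 genes, 435 higher and 350 lower (55.4% higher, 45.3% under library totals and 44.2% by DESeq2). The count was 1471 with the replicate block, 76 in a fit of the 12 libraries alone, 401 or 484 without Rad21-/- LPS 8 h replicate 2 or 3, and 487 without Rad21-/- primed replicate 3.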

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

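Each test of an explanation here was chosen after the result had been seen, while the differences between responses were planned.

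The results singled out here are the differences of a response between genotypes, each tested as an interaction. For LPS at 2 h 55 genes differed, with list medians of -1.32 (early LPS response), -0.84 (late LPS response, -0.835 before rounding), 0.27 (type I interferon), 0.36 (IFN-γ response), 0.73 (MHC class II) and -0.32 (mitochondrially encoded), and with Plat -6.30, Ptgs2 -3.73, Ccl3 -2.70, Egr1 -3.06, Il10 -3.45 and Slamf7 3.56. For LPS at 8 h 2425 genes differed, with medians of -1.21 (early), -0.84 (late), -0.59 (IFN-γ response), -0.87 (glycolysis and hypoxia) and 0.98 (cholesterol synthesis), and with Bmp2 6.52, Ednrb 4.89, Fst -6.16, Slamf1 -6.08, Il10 -5.29, Nos2 -3.78, Ptges -4.29, Ptgs2 -3.67, Ier3 -1.99, Zfp36 -2.86, Dusp2 -3.68, Hif1a -2.55, Pfkfb3 -4.51, Dhcr7 2.71, Mvk 1.42, Ifnar2 -1.76 and Cdkn1a -1.72.

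For priming at LPS 2 h 79 genes differed, with medians of 0.31 (early), 0.81 (late), 0.29 (type I interferon), 0.69 (IFN-γ response), -1.69 (MHC class II) and 0.40 (ribosomal proteins), and with Ank2 4.96, Fcgr4 2.48, Cnn3 -4.80 and Kynu -3.51. For priming at LPS 8 h 785 genes differed, with medians of -0.31 (early), 0.89 (type I interferon), 1.84 (IFN-γ response), -1.0 (MHC class II), -1.48 (proliferation), 0.48 (glycolysis and hypoxia), -0.92 (cholesterol synthesis), -1.63 (fibroblast) and 0.15 (ribosomal proteins), and with Ank2 5.40, Cxcl11 4.43, Fcgr4 3.29, Nlrc5 2.19, Ifi47 2.17, Dhx58 1.30, Eif2ak2 1.23, Cenpa -4.12, Lpin1 -5.23, S1pr3 -5.17 and Mvd -2.09. Without wild-type primed LPS 8 h replicate 2 the priming difference at 8 h was not called for the early (median -0.14, camera adjusted p = 0.12), glycolysis and hypoxia (0.36, adjusted p = 0.23) and fibroblast lists (-0.80, adjusted p = 0.25), and cholesterol synthesis moved to -0.39 (adjusted p = 0.038).

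The lists in both paragraphs above were called by camera with a preset correlation (adjusted p of 0.042 or less). With an estimated correlation the early list at LPS 2 h (adjusted p = 0.0033) and the IFN-γ response list for priming at 8 h (adjusted p = 0.019) kept the call, and each of the others lost it (adjusted p of 0.165 or more).

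Other splits of the same libraries were counted for each contrast, in fits of the compared groups alone, so these counts differ from those of the fit of all 30 libraries, which serves for the mean of 5. With 3 libraries against 3 there are 10 splits, too few for a share under 0.05; 1 split, the real one, gave the most calls in each. Real and highest other counts were 2716 and 1 (unstimulated genotype), 2375 and 1 (LPS 2 h), 4953 and 0 (LPS 8 h), 3102 and 0 (primed 2 h), 3666 and 0 (primed 8 h), 3410 and 0 (LPS 2 h in wild-type), 6750 and 0 (LPS 8 h in wild-type), 2878 and 0 (LPS 2 h in Rad21-/-), 6474 and 0 (LPS 8 h in Rad21-/-), 2454 and 0 and 214 and 0 (priming in wild-type at 2 h and 8 h), and 3364 and 0 and 3232 and 0 (priming in Rad21-/-). For the mean of 5, 1 of 60 splits reached 8554 calls and the highest other gave 1743. These splits and the fit treat libraries as independent, although those of the same replicate number correlate (mean r of 0.327). Moving the 5 libraries of a genotype and number together, added after this was seen, leaves 6 sets and 10 splits, too few for a share under 0.05 (8554 calls, highest other 1941). For the differences between responses 40 splits were drawn, and chance could not be excluded by them: 2 gave as many calls at LPS 2 h (64, highest other 4761), 4 at LPS 8 h (2342, highest other 6008), 3 for priming at 2 h (167, highest other 5000) and 2 for priming at 8 h (76, highest other 6932). These high splits exchange the genotypes within 1 stimulation and so measure the genotype difference, a structure of the samples. Among 82 splits balanced over genotype, added after this was seen, the real one alone gave as many and the highest other gave 0, which is partly built in because mixing genotypes widens the spread within arms.

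Wild-type primed LPS 8 h replicate 2 lies apart in components 1 and 2. Over wild-type LPS 8 h, primed LPS 2 h and replicates 1 and 3, 13 genes were at least 8-fold higher at LPS 2 h. Replicate 2 exceeded every library of these 3 sources in 12 of them, against weaker priming alone or an earlier harvest alone. Their upper quartile of 0.606 of the LPS 2 h level argues against exchange of the whole library. Their median share of 0.535 (0.510 for 66 genes at a 4-fold limit) leaves a mixture with wild-type LPS 2 h RNA or reads as a candidate. Weaker priming with earlier harvest stays open, and unstimulated cells were not compared.

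Genes at least 8-fold apart between genotypes in all 5 stimulations numbered 101, 71 higher and 30 lower in Rad21-/-. Of these 25 lay within 1 Mb of another, against a mean of 15.3 in 10000 random lists (highest 34, 1-sided permutation p = 0.034). The random lists ignored families of neighbouring genes, such as Slfn3 and Slfn4, and the set holds Rad21 itself. DNA of another strain around some loci may account for part of the set, but the excess alone does not single it out. Of the set 6, among them Ifi202b and Pydc4, lay within 3 Mb of chromosome 1, a window chosen after the values were seen. Slamf1, Slamf7, Slamf8, Ifi204 and Ifi205 lie there too, so the same explanation stays open for their genotype differences. Pseudogenes made up 34.7% of the set against 3.20% of tested genes (Fisher exact p = 3.2e-27) and all 35 were higher. They were not compared with their parent genes, so this share cannot tell whether reads shared with parents play a part. No label gives the strain, and the loss of Rad21 itself was not separable from the line.

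Type I interferon genes were lower in unstimulated Rad21-/- cells, with a median of -1.58. The median lay at -1.55 relative to that of all genes (library totals). A library factor moves both alike, so scaling does not account for this gap, while absolute amounts stay open without spike-ins. The list lay at -0.95 relative to the macrophage identity median (p = 7.0e-05, 100000 2-sided permutations of genes). Genes are not independent, so fewer macrophages as the whole cause stay open. Whether less interferon was made stays open, since Ifnb1 had 4 counts in the 3 Rad21-/- and 15 in the 3 wild-type libraries. A biological effect of the deletion stays a hypothesis.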

How the results depend on the processing

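Alternatives were planned, except those stated as added after the data were seen. Of 320 gene and contrast pairs named, 282 were called and 21 of these lost the call under at least 1 alternative. This tally does not measure robustness, since list and size genes whose call ended when 1 library was left out had been passed over. Of 141 called list results 15 kept the call with an estimated correlation and 126 lost it, 103 kept it by fry and 140 with the replicate block, and none changed direction. Without wild-type primed LPS 8 h replicate 2, 28 of 33 called list results of the 4 contrasts that use it kept the call, 5 lost it and 1 other gained it. The share of inducible genes lower in Rad21-/- stayed above that of random lists under each other alternative run, at 22.7% to 36.3% at 2 h and 47.6% to 57% at 8 h. Library totals, which raise the share of higher calls, were not run for it. Choosing inducible genes in wild-type alone gave 34.7% and 63.9% and is left out of these ranges, since the same wild-type LPS libraries then enter the choice and the difference, which builds in an excess of lower genes. Under library totals the LPS 8 h difference called 4045 genes, and Smc1a (0.0082), Mau2 (0.11) and Wapal (0.21) changed sign over the mean of 5. With the replicate number as a block (paired) the counts were 137 for the LPS 2 h difference, 3680 for LPS 8 h and 2956 for priming at 8 h in wild-type. They were 329 and 1471 for the priming differences at 2 h and 8 h, and over the mean of 5 the block called Ifnb1, Wapal and Esco1. The LPS 8 h difference and the mean of 5 use the pair of libraries at or under 0.1, so their block values are less certain. In fits of the compared groups alone, which have fewer libraries, the counts were 3666 for genotype in primed cells at 8 h, 214 for priming at 8 h in wild-type, and 167 and 76 for the priming differences. DESeq2 called 145 for the LPS 2 h difference and 254 for the priming difference at 2 h. Leaving out 1 library gave 23 to 56 for the LPS 2 h difference, 36 to 142 and 401 to 1080 for the priming differences at 2 h and 8 h, and 1059 to 2624 for priming at 8 h in wild-type. The cause was not tested for any of these moves. In 17 of 18 contrasts the majority direction of the calls turned under at least 1 alternative, the LPS 2 h difference being the exception (16.1% to 48.5% higher), so the balance of directions depends on scaling and on single libraries. Other contrast counts stayed within 1.5 times of the main count under each alternative run. Not run were spike-in scaling, without spike-in rows, and a fit of the compared groups alone for the mean of 5, which uses all groups. What depth alone limits was not tested.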

Other observations

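Tests in this part were chosen after the results had been seen.

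Xist, which is transcribed from the inactive X chromosome, stood at 231 to 441 CPM in replicate 3 of all 10 groups and at 0.035 CPM or less in replicates 1 and 2. The Y-linked gene Ddx3y stood at 52.8 to 166 CPM in replicates 1 and 2 and at 0.059 CPM or less in replicate 3, and Eif2s3y, Kdm5d and Uty had 0 counts in replicate 3. No label gives sex, but these values argue against replicate 3 sharing animals with replicates 1 and 2. Each comparison holds the same replicate numbers on both sides. AY036118 took 3.22% of the counts of wild-type primed LPS 8 h replicate 1, the smallest library, and stood at 32210 CPM there, 9822 CPM in unstimulated Rad21-/- replicate 3 and 8916 CPM in primed LPS 8 h Rad21-/- replicate 1.

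The hypothesis that the deficit of inducible genes in Rad21-/- grows with the size of their induction was tested by rank correlation across genes. Spearman's rho was -0.15 at 2 h and -0.12 at 8 h, short of the bound of -0.2 set for it. The median log2 difference was -0.32 in the weakest and -0.86 in the strongest of 4 equal groups of inducible genes at 2 h, and -0.74 and -1.30 at 8 h, while the percent of genes called lower was 25.4 and 31.9 at 2 h and 54.5 and 51.2 at 8 h.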
